A study of Caenorhabditis elegans with 6 samples.

How the data were processed

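RNA was measured in sterile C. elegans adults of 2 genotypes, with 3 samples of each. The mes-1(bn84ts) worms lack a germline, and the daf-2(e1370); mes-1(bn84ts) worms carry in addition a reduction-of-function allele of the insulin/IGF-1 receptor gene. Per the labels' protocols, embryos were laid at 24°C, moved to 15°C on day 1 so that daf-2 larvae did not become dauers, and returned to 24°C as adults on day 5. On day 6, 100 adults without visible embryos were picked by hand for each sample. Total RNA was depleted of ribosomal RNA with a kit made for human, mouse and rat RNA, and libraries were made with a kit that does not mark strand, per the labels' protocols. The labels number the samples within each genotype but do not say whether they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

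The data used here are 1 table of 20422 genes on chromosomes I to V and X. TopHat2 and DESeq2 are named in the submitters' processing notes without versions, and Cuffdiff2 is named in the file headers. The genome build and annotation behind the table are not given in the sources used here. Gene positions are printed as the table gives them, and no coordinate of another build is printed. The table holds 5 columns of values and no value for a single sample. The signal column is the mean normalized count over all 6 samples, made by the authors with DESeq2 per the file headers. The log2 column is the deposited log2 fold change of daf-2; mes-1 over mes-1, from DESeq2 per the file headers. It ends at an absolute value of 5, which 2 genes reached. The p-value column holds the deposited Benjamini-Hochberg adjusted p-values, from DESeq2 per the file headers. It ends at 1e-20, which 22 genes reached. The RPKM columns hold the authors' Cuffdiff2 value for each genotype, per the file headers, and are printed as the authors' values with no SD or n. Across 9820 genes with an adjusted p, log2 fold changes and log2 RPKM ratios had r = 0.976. Some fold changes lie much nearer 0: pos-1 has -0.58, with RPKM of 14.5 in mes-1 and 1.53 in daf-2; mes-1. With only 1 read, fer-1 has 0.19. Medians over all members with a fold change take in such genes, so a weaker median there need not mean a weaker change.

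The comparison was planned, before the data were examined, as a count test of the 6 samples, with camera for the gene lists. The plan said that values would be described as deposited, with no new test, if only the authors' comparison was found. That was the case, so calls are the authors' own: a gene was called when its deposited adjusted p from DESeq2 was under 0.05. The gene lists, the rule for named genes, the threshold and the first set of other settings were fixed before the data were examined. Lists were matched by gene ID to present symbols, and 19180 of the 20422 gene IDs had one. The rule named 6 genes with the largest change in each direction among called genes with a mean of at least log2 CPM 1, where CPM is the mean as a share of all means. It also named 8 fixed genes and the 2 called members of each list with the largest change. Its requirement that replicates of the genotypes do not overlap could not be applied. Members beyond that rule which are named as examples were chosen after their values were seen.

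Unadjusted p-values were bounded from above by inverting the Benjamini-Hochberg adjustment, and each list was then adjusted over the list alone from these bounds. The bound also gave an implied standard error, the size of the log2 fold change divided by the normal quantile of the bound. The median log2 fold change of each list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list outside percentiles 2.5 and 97.5 is said to stand apart. This describes the table and is not a p-value, since it takes genes as independent. Of 29 lists with at least 2 genes with an adjusted p, 17 stood apart, where 1.45 would by chance. These 17 are not separate results, because lists share genes. The pooled germline list holds the 5 germline lists. The DAF-16 lists share members with the heat shock, glyoxylate, yolk, immunity, lipid and insulin-like peptide lists. The immunity and C-type lectin lists share members too. Of 100 lists of 25 genes drawn at random from the table itself, 5 stood apart, and all 100 did once shifted by 0.5 on the log2 scale. A share near 5 of 100 follows from the way such lists are drawn, so it does not check lists of genes that change together. The bounds were never below the simulated p over 9820 simulated genes.

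The depth of each library was partly recovered from the means, which are given with 10 significant digits. Genes with very few reads take values that are sums of whole multiples of 6 steps, each the worth of 1 read in 1 library divided by the number of samples. All genes whose mean follows from a single library's step had the same sign of log2 fold change, and the RPKM columns name the genotype, so 3 steps belonged to mes-1 and 3 to daf-2; mes-1. Which numbered sample each step belongs to is not known. Of 8228 genes with a mean above 0 and under 10, 8227 had exactly 1 set of reads within a tolerance of 1.2e-09. On simulated data, 99.93% of 7026 such genes had 1 solution, and all of those equalled the simulated reads. The size factors were 1.79, 0.859 and 0.826 for the mes-1 libraries and 1.38, 1.07 and 0.584 for daf-2; mes-1, a range of 3.06 times. Higher means allow too many solutions, so per-library values exist only for genes of low expression and no count model was run on them. Sums over such genes of a list were compared by an exact two-sided permutation test over the 20 assignments of 6 libraries, whose smallest p is 0.1.

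Precision rose with expression. Among the lowest quartile of genes with an adjusted p, with means from 5.75 to 16.5, 4.89% were called and the smallest called change was 1.36 on the log2 scale. In the highest quartile, with means of at least 111, 19.3% were called and the smallest called change was 0.55. Without strand, reads of overlapping genes cannot be told apart, and 185 of the called genes have exons that overlap another gene on the opposite strand in Ensembl release 115 of WBcel235, matched by gene ID. Genes of multigene families are uncertain where copies are nearly identical. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. No result was left out for its direction. The mitochondrially encoded genes are not in the table and were not analysed here.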

Results

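The table compared whole sterile adults that differ in insulin/IGF-1 receptor signalling, and the labels state an interest in germline genes that become active in somatic tissue. Each genotype, mes-1 and daf-2; mes-1, had 3 samples of 100 worms. The total number of reads of each sample is unknown, but the recovered size factors place the deepest library 3.06 times above the shallowest. All fold changes are daf-2; mes-1 over mes-1, and gene positions refer to a genome build that is not given in the sources used here.

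Sterile adults with the daf-2 mutation differed from mes-1 adults in both directions, with more genes lower than higher. Of 9820 genes with an adjusted p in the authors' deposited table, 1009 (10.3%) were called by DESeq2, 385 higher and 624 lower in daf-2; mes-1. An absolute log2 fold change of at least 1 was reached by 273 of the higher and 496 of the lower genes. The median log2 fold change of all genes with an adjusted p was -0.03. The mutated genes carry point mutations, so their RNA level does not check the labels. In the authors' deposited table daf-2 had a log2 fold change of 0.35 (adjusted p = 0.615, DESeq2) and mes-1 one of 0.98 (adjusted p = 0.283). For daf-16, the FOXO transcription factor that daf-2 restrains, the authors' deposited table gave 0.20 (adjusted p = 0.82).

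The largest rises were in D1086.9, alh-2, F08H9.4, Y110A2AL.2, ZK355.3 and col-50, with log2 fold changes of 5.00, 5.00, 4.78, 4.59, 4.21 and 4.20 in the authors' deposited table. D1086.9 (WBGene00008396) was the most abundant of them. Its RPKM in the authors' deposited table was 25.2 in mes-1 and 3025 in daf-2; mes-1, and its log2 fold change sits at the limit of the table. The gene lies on chromosome V from 14104255 to 14106466. The largest falls were in cyp-35A3, dod-23, cyp-14A3, R193.2, oac-20 and ugt-53, with log2 fold changes of -5, -4.83, -4.82, -4.48, -4.46 and -4.32 in the authors' deposited table. For cyp-35A3, a cytochrome P450 gene on chromosome V from 4022604 to 4024458, the authors' deposited table gave RPKM values of 39.4 in mes-1 and 0.062 in daf-2; mes-1. All 12 of these genes had an adjusted p of 2.27e-14 or less in the authors' deposited table (DESeq2). The exons of oac-20 overlap those of fbxa-99 on the opposite strand.

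Called targets of DAF-16 mostly moved in the direction of their class, with exceptions in the activated class. Of 27 measured members of the DAF-16 activated list (class I), 8 were higher, 3 lower and 16 not called in the authors' deposited table. When adjusted over the list alone the counts were 11 and 3. The mitochondrial superoxide dismutase gene sod-3, on chromosome X from 17092644 to 17094149, rose 7.93-fold (log2 fold change 2.99, adjusted p = 2.16e-20, DESeq2) in the authors' deposited table. Its exons overlap C08A9.3 on the opposite strand, for which the authors' deposited table gave 4.07. The small heat shock protein genes hsp-12.3 and hsp-12.6 rose by 2.73 and 2.62 on the log2 scale, the heat-inducible hsp-70 by 2.15 and the linker histone gene hil-1 by 1.78, per the authors' deposited table. The called falls of this list were aqp-1, an aquaglyceroporin gene, the metallothionein gene mtl-2 and the catalase gene ctl-1, with log2 fold changes of -2.05, -1.84 and -0.70 in the authors' deposited table. The list median was 0.59, at percentile 100 of the random lists.

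All 9 measured members of the DAF-16 repressed list (class II) fell in the authors' deposited table, and all 9 did when adjusted over the list alone. Their median was -2.31, at percentile 0, and -1.52 over all members with a fold change. The strongest were dod-23 and dod-24, whose names stand for downstream of DAF-16, with log2 fold changes of -4.83 and -3.81 in the authors' deposited table. The list was drawn from general knowledge of daf-2 mutants and shares vit-2 and vit-5 with the yolk genes. It also shares ins-7 with the insulin-like peptides, and dod-22 and dod-24 with the immunity list.

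The vitellogenin genes, which encode yolk proteins made in the intestine, took 34.1% of the summed mean normalized counts. Of the 6 genes, 5 fell in the authors' deposited table, and 6 did when adjusted over the list alone. The largest falls were those of vit-5 (log2 fold change -1.58, adjusted p = 8.06e-08) and vit-4 (-1.34, adjusted p = 1.2e-06) in the authors' deposited table (DESeq2). For vit-6, the authors' deposited table gave -0.47 with an adjusted p of 0.258. The yolk gene median was -1.06, at percentile 0.33. Of 13 measured intestine markers, 7 were also called lower, and the median of that list was -0.80.

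Of the insulin signalling components, 3 kinase genes were called, in both directions. In the authors' deposited table pdk-1 and akt-1 rose by 1.63 and 1.26 on the log2 scale, while sgk-1 fell by 1.46. Exons of pdk-1 overlap those of F21E9.2 on the opposite strand. The other 16 of the 19 measured insulin signalling components were not called, and the counts adjusted over the list alone were the same 2 and 1. The list median of 0.17, at percentile 95.6, did not stand apart, while the median over all members with a fold change, 0.19 at percentile 97.53, just did. Among 12 measured insulin-like peptide genes, 3 rose (ins-10, ins-29 and ins-30) and 2 fell (ins-19 at -3.21 and ins-7 at -2.95 on the log2 scale) in the authors' deposited table. Adjusted over the list alone, 4 rose and 2 fell, and ins-7 is also a member of the DAF-16 repressed list. The median of the insulin-like peptide genes was 0.62, at percentile 100. It was 0.15 over all members with a fold change, where it no longer stood apart (percentile 97.4).

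Stress and defence genes changed in both directions. Of 22 heat shock protein genes, 3 rose and 3 fell in the authors' deposited table, with the same counts adjusted over the list alone. The risers were hsp-12.3, hsp-12.6 and hsp-70, all of them also members of the DAF-16 activated list. The fallers were hsp-4 and hsp-3, which encode chaperones of the endoplasmic reticulum, and hsp-17. The authors' deposited table gave -2.05 for hsp-4, and the list median was 0.21, at percentile 98.5 (0.03, at percentile 69.8, over all members with a fold change). Of 24 innate immunity genes, 9 fell and 1 rose in the authors' deposited table, and 9 and 2 did when adjusted over the list alone. The rise was in sek-1, a kinase gene of the p38 pathway, and the largest falls were in dod-24 and dod-22, with log2 fold changes of -3.81 and -3.58 in the authors' deposited table. Both dod genes also belong to the DAF-16 repressed list. The median of the immunity list was -0.44, at percentile 0.04.

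C-type lectin genes, a large family with many members induced by infection, were mostly lower where called. The authors' deposited table called 24 of 67 lower, led by clec-218 (-3.60) and clec-265 (-3.40), and 1 higher, clec-76 (3.18). Adjusted over the list alone, 31 were lower and 3 higher. The list median was -0.64, at percentile 0, and -0.28 over all members with a fold change, also at percentile 0. Reads recovered for 102 lectin genes with a mean normalized count under 10 summed to 233 ± 9.86 normalized reads in mes-1 and 117 ± 9.51 in daf-2; mes-1 (SD, n = 3 each). An exact permutation test gave p = 0.1, the smallest possible, or 0.433 after Benjamini-Hochberg adjustment over 13 lists compared in this way. The families are large, and near-identical copies may share reads.

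Detoxification families moved in both directions. For cytochrome P450 genes, the authors' deposited table called 5 of 50 higher and 16 lower, or 6 and 17 adjusted over the list alone. The falls included cyp-35A3, cyp-14A3 and other members of the cyp-35A group, and the rises were cyp-13B1, cyp-33C2, cyp-13A11, cyp-13A5 and cyp-33D1. The list median of -0.13, at percentile 6.39, did not stand apart, nor did the median over all members with a fold change (percentile 62.5), but the median RPKM ratio of -0.20, at percentile 0.69, did. Among 51 UDP-glucuronosyltransferase genes, 8 rose and 9 fell in the authors' deposited table, or 11 and 9 adjusted over the list alone. Of these ugt-1 rose by 2.12 and ugt-53 fell by 4.32 on the log2 scale, per the authors' deposited table. The list median was -0.18, at percentile 1.31, and the median RPKM ratio of -0.14, at percentile 4.75, no longer stood apart. The median over all members with a fold change was -0.20, at percentile 0.28. Glutathione S-transferase genes were called higher in 5 of 27 cases and lower in 1 in the authors' deposited table, or 6 and 1 adjusted over the list alone. The rises were gst-3 (2.77), gst-41 (2.57), gst-4, gst-1 and gst-39, the fall was gstk-1, and the list median of 0.15, at percentile 96.2, did not stand apart, while the median RPKM ratio of 0.17, at percentile 97.6, and the median over all members with a fold change of 0.19, at percentile 99.2, did.

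Cuticle collagen genes were mostly higher where called. The authors' deposited table called 17 of 65 higher and 4 lower, or 19 and 4 adjusted over the list alone. The largest changes were those of col-50 (log2 fold change 4.20) and col-135 (-3.45) in the authors' deposited table, and the other falls were col-43, col-70 and col-158. The list median was 0.38, at percentile 100, and 0.15 over all members with a fold change (percentile 99.9).

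Metabolic genes changed in part. Of 33 lipid metabolism genes, 4 rose and 7 fell in the authors' deposited table, or 6 and 9 adjusted over the list alone. The rises included lbp-8, which encodes a lysosomal lipid chaperone, and the lysosomal lipase gene lipl-4, with log2 fold changes of 2.28 and 1.87 in the authors' deposited table, and the lipid synthesis genes fat-6 and pod-2. The falls included the lipase gene lipl-3 (-2.17) and the peroxisomal beta-oxidation genes acox-1 (-1.73), daf-22 (-1.06) and dhs-28 (-0.94) in the authors' deposited table. The list median was 0.12 and its mean -0.11, and at percentile 93.8 the median did not stand apart. Over all members with a fold change the median was 0.19, at percentile 98.5, and did. Among 22 genes of glyoxylate, gluconeogenesis and trehalose metabolism, 3 rose and 2 fell in the authors' deposited table, or 6 and 3 adjusted over the list alone. The falls were the trehalase genes tre-3 and tre-2, with log2 fold changes of -1.53 and -0.93, and the rises were the trehalose synthesis gene tps-1 (0.90), pck-1 (W05G11.6; 0.88) and pygl-1 (T22F3.3; 0.55), per the authors' deposited table. The median of this list was 0.30, at percentile 99.8.

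None of the large housekeeping complexes had a called member in DESeq2's test, but the medians of oxidative phosphorylation and ribosomal protein genes stood apart. All 29 oxidative phosphorylation genes had positive log2 fold changes in the authors' deposited table, with a median of 0.28 at percentile 99.9. Of 74 cytosolic ribosomal protein genes, 71 had negative values in the authors' deposited table, with a median of -0.26 at percentile 0.02. The 33 proteasome genes had a median of 0.05, at percentile 85.4. At a bounded unadjusted p under 0.05 the counts were 3 higher for oxidative phosphorylation, 1 higher and 2 lower for ribosomal proteins, and 1 higher for the proteasome (rpn-8). Adjusted over the list alone, all were 0.

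**Figure D1:**
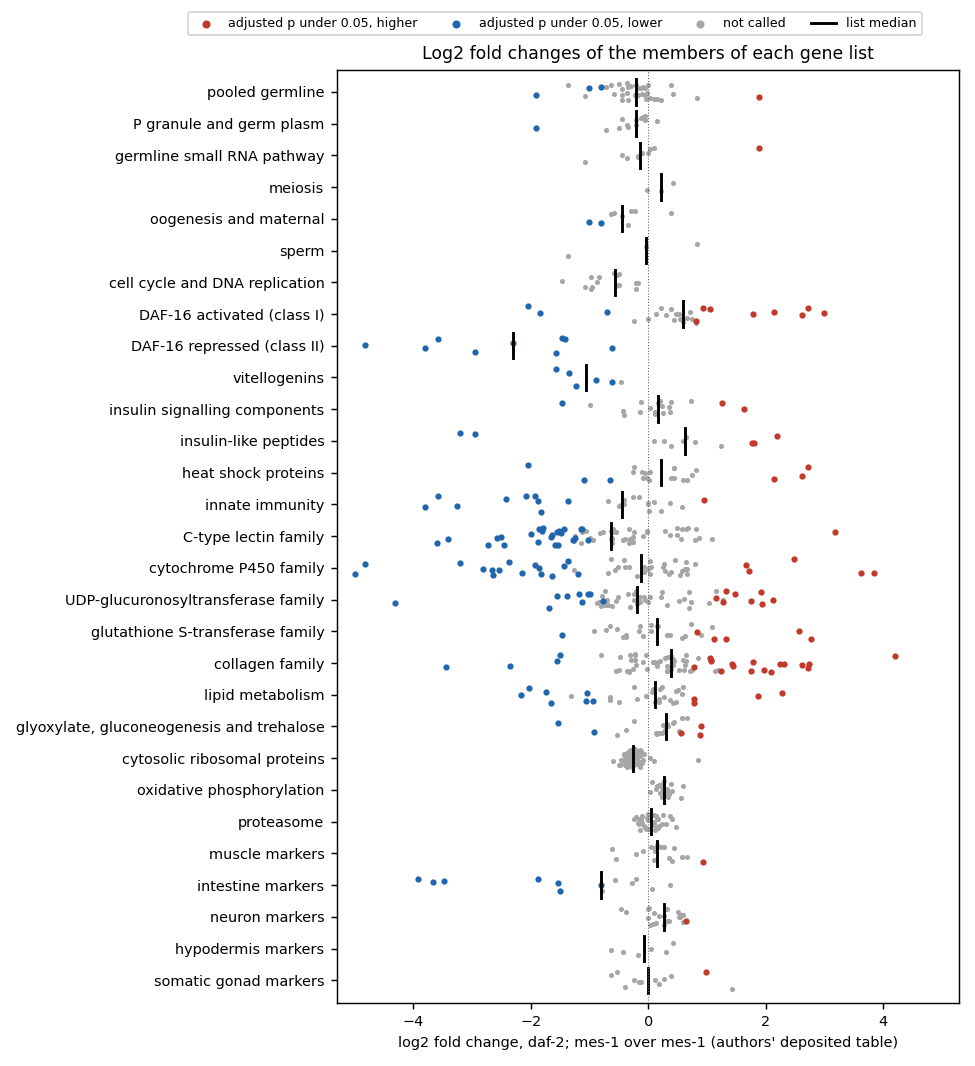
Log2 fold changes of daf-2; mes-1 over mes-1 (x axis) of each member with an adjusted p, for 29 gene lists (rows), from the authors' deposited table. Each point is a gene, coloured when its adjusted p was under 0.05, and black bars are list medians: the DAF-16 repressed list has its median at -2.31 and the activated list at 0.59.

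Tissue markers moved unequally. Of 13 measured intestine markers, 7 fell and none rose in the authors' deposited table, or 8 and 0 adjusted over the list alone. The oligopeptide transporter gene pept-1 (log2 fold change -3.93, adjusted p = 4.1e-16), the acid phosphatase gene pho-1 (-3.67, adjusted p = 5.3e-16) and the intermediate filament gene ifb-2 (-3.49, adjusted p = 1e-20, the limit of the table) fell most in the authors' deposited table (DESeq2). In contrast, the authors' deposited table gave 0.06 for the intestinal GATA factor gene elt-2 and 0.37 for the gut esterase gene ges-1, both not called. Exons of pho-1 overlap those of EGAP2.1 on the opposite strand. The intestine median was -0.80, at percentile 0.01. Of 22 neuron markers, the synaptobrevin gene snb-1 was called higher in the authors' deposited table (log2 fold change 0.64, adjusted p = 0.0367, DESeq2), but none was when adjusted over the list alone. The neuron median was 0.27, at percentile 99.7 (96.2 for RPKM ratios with a pseudocount of 5). Of 18 muscle markers, the myosin gene myo-3 was the only one called in the authors' deposited table, at 0.93, also when adjusted over the list alone, and the median of 0.16 at percentile 92.3 did not stand apart. Of 12 somatic gonad markers, egl-13, a SOX factor gene, was called at 0.99 in the authors' deposited table, also when adjusted over the list alone. Its list median was -0.01, at percentile 57.2, and turned positive with RPKM ratios. None of 6 hypodermis markers was called by DESeq2 or had a bounded unadjusted p under 0.05, and their median was -0.07, at percentile 43.3.

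Of the germline genes with an adjusted p 10.5% were called, and of all genes 10.3%, a share that rose with expression and was not tested for a difference. The 5 germline lists together held 118 genes of the table, of which 38 had an adjusted p. Of these, 1 was higher and 3 were lower in daf-2; mes-1 in the authors' deposited table, and the counts adjusted over the list alone were the same. The rise was in csr-1, an Argonaute gene of the germline small RNA pathway on chromosome IV from 7957568 to 7962109. It rose 3.70-fold (log2 fold change 1.89, adjusted p = 2.54e-13, DESeq2), with RPKM values of 29.5 in mes-1 and 114 in daf-2; mes-1 in the authors' deposited table. Its exons overlap those of F57H12.4 on the same strand, which had a mean normalized count of 1.19 in the authors' deposited table. The falls were those of nos-2, a nanos-related gene of the germ plasm (log2 fold change -1.91, adjusted p = 0.0262), and of the eggshell genes perm-4 (C44B12.5 in the table; -1.02, adjusted p = 2.97e-04) and perm-2 (C44B12.1; -0.81, adjusted p = 0.00115), in the authors' deposited table (DESeq2). In the authors' deposited table the RPKM in mes-1 and daf-2; mes-1 was 1392 and 674 for perm-4 and 2008 and 1134 for perm-2. The RPKM of all 118 genes summed to 3953 and 2239, and perm-4 and perm-2 made up most of both sums. RNA of whole worms does not show whether csr-1, perm-4 and perm-2 were expressed in germline or somatic cells. With the genes whose exons overlap another on the opposite strand left out, which are nos-2 (within him-14) and perm-2, 1 fall was left. The pooled median was -0.21, at percentile 1.76. Where reads per library were recovered, leaving out 1 library reversed the direction: over 71 germline genes, the median log2 ratio of daf-2; mes-1 to mes-1 was -0.47, 0.31 without the deepest mes-1 library and -0.02 without the deepest library of both genotypes.

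By list, the P granule and germ plasm genes had 0 of 13 higher and 1 lower (nos-2), the small RNA pathway genes 1 of 10 higher and 0 lower (csr-1), and the oogenesis and maternal genes 0 of 9 higher and 2 lower, in the authors' deposited table. Adjusted over the list alone these counts were the same. The oogenesis median was -0.45, at percentile 1.38 (-0.82 with RPKM ratios). Over genes with an adjusted p, the deposited medians of -0.21 for P granule genes (percentile 9.19) and -0.14 for small RNA genes (percentile 23.8) did not stand apart. The P granule list did stand apart with RPKM ratios of pseudocount 1 (percentile 1.6) and over all members with a deposited fold change (-0.36, percentile 0.35). The 4 oogenesis genes with recovered reads summed to 132, 11.65 and 2.42 normalized reads in mes-1, deepest library first, and 26.01, 0 and 0 in daf-2; mes-1. The means were 48.7 and 8.67, or 7.03 and 0 without the deepest library of each genotype. None of 3 meiosis genes and 3 sperm genes was called by DESeq2 in the authors' deposited table. Adjusted over the list alone, 1 sperm gene, ssp-10, was lower, and at a bounded unadjusted p under 0.05 it was also the only one of the 6. The medians were 0.21 for meiosis (percentile 82.1) and -0.03 for sperm (percentile 46.6), and both changed sign in other settings. The 16 cell cycle and DNA replication genes all had negative log2 fold changes in the authors' deposited table, with a median of -0.57 at percentile 0.02. The reads of 12 low-expressed members had a mean sum of 112 in mes-1 and 44.8 in daf-2; mes-1, and 32.9 and 24.5 without the deepest library of each genotype. With only the deepest mes-1 library left out the order turned, at 32.9 in mes-1 against 44.8 in daf-2; mes-1. None of the 16 genes was called by DESeq2 or adjusted over the list alone, and 1, cyb-3, had a bounded unadjusted p under 0.05. No major sperm protein gene of 30 and no early zygotic embryo marker of 17 reached an expression with an adjusted p.

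For the P granule genes fixed in advance, the authors' deposited table gave log2 fold changes of -0.44 for pgl-1 (adjusted p = 0.849), 0.14 for glh-1 (adjusted p = 0.969) and -0.05 for pie-1 (adjusted p = 0.99, DESeq2). For pgl-3 the authors' deposited table gave -0.28 without an adjusted p. Their RPKM was low: glh-1 had 4.06 in mes-1 and 3.68 in daf-2; mes-1 in the authors' deposited table. For pie-1 the authors' deposited table gave RPKM values of 3.29 in mes-1 and 3.15 in daf-2; mes-1. The RPKM of pgl-1 was 4.51 in mes-1 and 1.56 in daf-2; mes-1 in the authors' deposited table, and that of pgl-3 2.32 and 0.693. For pgl-1 and pgl-3 the RPKM thus fell by more than the deposited log2 fold changes give. Per-library reads could be recovered for pgl-3 and pie-1. In the 3 mes-1 libraries, deepest first, pgl-3 had 22.4, 0 and 0 normalized reads, and in daf-2; mes-1 it had 3.61, 1.87 and 0. The values of pie-1 were 17.9, 0 and 7.26, and 11.6, 4.68 and 8.56. Exons of pie-1 overlap those of snr-6 on the opposite strand, so the pie-1 values may include reads of snr-6. The values of nos-2 were 25.2, 3.49 and 4.84, and 2.17, 0 and 0.

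The germline signal was uneven between libraries of the same genotype. Over 71 germline genes of low expression (a mean normalized count under 10), recovered reads summed to 646, 146 and 88.4 normalized reads in the mes-1 libraries, deepest first. In daf-2; mes-1 they summed to 268, 117 and 92.4. The means were 293 ± 306 and 159 ± 95.1 (SD, n = 3 each; exact permutation test, two-sided p = 0.7, adjusted p = 0.827 over the 13 lists). Cell cycle genes of low expression followed with 272, 51.2 and 14.5 in mes-1 and 85.3, 33.7 and 15.4 in daf-2; mes-1. Among 51 germline genes with over 5 normalized reads in mes-1, the deepest mes-1 library held the largest mes-1 value for 48. Sperm genes of low expression differed by less than the spread between libraries, at 26.4 ± 8.58 in mes-1 and 31.8 ± 8.29 in daf-2; mes-1 (SD, n = 3 each; exact permutation test, p = 0.5, adjusted p = 0.812). The authors' calls could not be recomputed without any library, because genes of higher expression have no values per library here. Insulin-like peptide genes of low expression summed to 53.7 ± 11.1 in mes-1 and 79.5 ± 3.41 in daf-2; mes-1 (SD, n = 3 each; exact permutation test, p = 0.1, the smallest possible, adjusted p = 0.433).

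**Figure D2:**
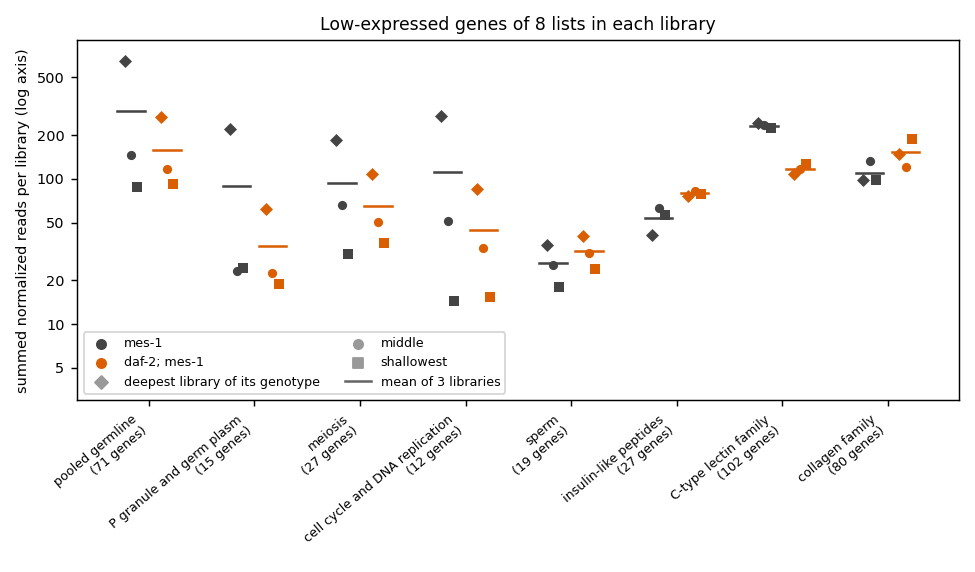
Summed normalized reads (y axis, log scale) of the low-expressed members of 8 gene lists (x axis) in each of the 3 mes-1 and 3 daf-2; mes-1 libraries. Points are libraries, shaped by depth within their genotype, and lines are means of 3: pooled germline genes reach 646 in the deepest mes-1 library against 146 and 88.4 in the others, while C-type lectin genes lie at 233 ± 9.86 in mes-1 and 117 ± 9.51 in daf-2; mes-1.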

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

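The test of the intestine markers, and the values with libraries left out, were chosen after the results were seen; the tests of the germline pattern were written before the reads per library were recovered.

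A set of 37 genes had no adjusted p although their mean normalized count was at or above that of genes with one. They enter no call and no median over genes with an adjusted p; those with recovered reads enter the sums and ratios of low-expressed genes, and list members among them the medians over all members. Of the 37, 36 had a lower RPKM in daf-2; mes-1 in the authors' deposited table, and 14 belong to the oogenesis and maternal list. They include the eggshell genes cpg-1 (RPKM 38.4 in mes-1 and 5.49 in daf-2; mes-1 in the authors' deposited table), cpg-2 (25.2 and 4.33) and cbd-1 (15.3 and 2.70), the yolk receptor gene rme-2 (6.60 and 0.975) and the maternal genes puf-5, spn-4, mex-3, mex-5 and oma-2. The exception is C54F6.15, with RPKM values of 0.753 in mes-1 and 233 in daf-2; mes-1 in the authors' deposited table. For 16 of the 37 reads per library were recovered, and all 16 had their largest normalized value in the deepest mes-1 library. Their reads numbered 997 there and 32 in the other mes-1 libraries together. The normalized sums were 558, 30.3 and 7.26 in mes-1 and 103, 17.8 and 11.98 in daf-2; mes-1. Why the 37 genes have no adjusted p was not tested. If genes with an extreme value in 1 library were left without one, this concentration follows from that choice. Only the identity of the library would then be a result.

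A candidate explanation for the higher oogenesis RPKM in mes-1 is germline RNA in a single mes-1 library, for example from a worm that kept some germline. Among 51 germline genes with over 5 normalized reads in mes-1 the median share in the deepest mes-1 library was 76.21% (quartiles 50.4 and 92.7), against 33.3% for equal levels and 32.5% over 3451 other genes. Lower expression in every daf-2; mes-1 library than in every mes-1 library is argued against by the sums over the 71 germline genes of low expression. The 2 other mes-1 libraries, at 146 and 88.4, lay under the deepest daf-2; mes-1 library, at 268. Among the 51 genes these 2 lay at a median of 0.7151 times the daf-2; mes-1 mean (quartiles 0.337 and 0.965, over the 50 with reads in daf-2; mes-1). That mean holds the deepest daf-2; mes-1 library, which lowers the ratio, so the ratio decides nothing beyond this ordering. A fall in daf-2; mes-1 beyond the deepest libraries stays open. With the deepest of each genotype left out, the median log2 ratio of daf-2; mes-1 to mes-1 over all 71 germline genes with recovered reads was -0.0156, with 36 genes higher in mes-1 and 25 in daf-2; mes-1. Over the 51 genes, whose filter favours mes-1, it was -0.177, with 31 genes higher in mes-1 and 17 in daf-2; mes-1. The 4 oogenesis genes with recovered reads had mean sums of 7.03 in mes-1 and 0 in daf-2; mes-1. Only 2 libraries of each genotype were left. Why the deepest mes-1 library differs stays open, since the deepest daf-2; mes-1 library is also the highest of its genotype and neither the handling of the samples nor their numbers can be read from the table.

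Another 109 genes had a mean normalized count of 0 and an RPKM above 0 in either genotype, and they enter no comparison of the report. The higher RPKM had a median of 0.629 and was at least 1 for 49 of them, and 60 have exons that overlap another gene. Some were highly expressed: gpd-2, a member of the DAF-16 activated and glyoxylate lists, had RPKM values of 785 in mes-1 and 1345 in daf-2; mes-1 in the authors' deposited table, and so was left out of both list medians. The desaturase gene fat-7 is also among them, with RPKM values of 1.51 in mes-1 and 1.01 in daf-2; mes-1 in the authors' deposited table.

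The lower median of the intestine markers raises the question whether daf-2; mes-1 worms held a smaller share of intestinal RNA. A smaller share would lower all markers by about the same factor. Of 13 members, 9 lay more than 2 implied standard errors from the weighted mean of -1.14, from pept-1 at -3.93 to ges-1 at 0.37, which argues against a smaller share as the whole cause. Regulation of single intestinal genes in daf-2 mutants remains a hypothesis, and it was not tested apart from a change in the worms' intestine.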

How the results depend on the processing

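All alternatives that could be run were chosen after seeing the data except the stricter threshold, the pseudocounts of 0.1 and 5 and the expression floor of list members. At an adjusted p under 0.01, 262 genes were higher and 471 lower, and 1 germline gene was higher and 2 were lower. Requiring an absolute log2 fold change of at least 1, no opposite-strand exon overlap or an RPKM of at least 1 left 273 to 385 higher and 496 to 624 lower. Germline genes higher stayed at 1 in all these settings, none of which left out same-strand overlaps such as that of csr-1. Germline genes lower numbered 1 in place of 3 without opposite-strand overlaps, because nos-2 and perm-2 overlap other genes. The pooled germline median ranged from -0.28 (all members with a fold change) to -0.16 (RPKM ratio, pseudocount 5) and stood apart in each, but none of these settings leaves out a library.

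The sperm median, -0.03 in the deposited fold changes, was 0.0496 with RPKM ratios (0.0792 and 0.0186 with pseudocounts of 0.1 and 5) and 0.0141 over all members with a fold change. The somatic gonad median, -0.01, was 0.0374 with RPKM ratios (0.0417 and 0.0188 with pseudocounts of 0.1 and 5), 0.0210 after centring on the median gene and 0.0501 over all members. The meiosis median, 0.21, was -0.15 over all members. The cause was not tested, and these lists rest on few genes with an adjusted p. Of the named genes only glh-1, which was not called, changed sign, from 0.14 to -0.11 with RPKM ratios (-0.14 and -0.06 with pseudocounts of 0.1 and 5). Over all members with a fold change, the P granule, insulin signalling, glutathione S-transferase and lipid lists also stood apart, and the insulin-like peptide and heat shock lists no longer did. Over the 71 germline genes with recovered reads, the median log2 ratio of daf-2; mes-1 to mes-1 (pseudocount 1) was -0.473. It was 0.311 without the deepest mes-1 library, -0.0156 without the deepest library of both genotypes, between -0.693 and -0.363 with any other library left out, and -0.761 over the 51 genes with over 5 normalized reads in mes-1, a filter that favours mes-1.

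The planned count tests, other normalizations, count filters, left-out samples for the calls, removal of dominant genes, test against a fold change, camera and fry were not run, because values per library exist only for genes with a mean under 10. Other splits of the samples were not counted for the same reason. No paired analysis was possible because the table holds no values for numbered samples. Of 118 germline genes 38 had an adjusted p, and 16 had none although their mean was as high as that of genes with one.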

Other observations

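All tests in this part were chosen after the calls were seen, except those of overlapping genes and of the region around daf-2, which were written before their results.

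Some gene families that were not themselves lists held more falls than expected by chance. Families were taken from shared name prefixes with at least 8 genes with an adjusted p, and 178 one-sided Fisher's exact tests were made, 1 for each family and direction. Short-chain dehydrogenase genes (dhs) were lower in 9 of 25 cases, where 1.59 would be by chance (adjusted p = 3.84e-04). Among these 9, dhs-28 also belongs to the lipid metabolism list. O-acyltransferase homologues (oac) were lower in 6 of 10 (0.635 by chance, adjusted p = 3.84e-04), with oac-20 at -4.46 in the authors' deposited table. The nspc genes, a family of small secreted proteins, were lower in 7 of 18 (1.14 by chance, adjusted p = 0.00176). The authors' deposited table also called dhs-13 (0.91) and oac-21 (1.95) higher, and most dhs and nspc genes were not called. These genes are clustered copies in part, so they are not independent.

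Called genes were spread unevenly over the chromosomes. On chromosome V 15.5% of 1905 genes with an adjusted p were called, against 9.02% elsewhere (Fisher's exact test, adjusted p = 1.06e-14 over the 6 chromosomes). On chromosome X the share was 12.8% (adjusted p = 0.00113), and it was lowest on chromosomes I and III, at 5.48% (adjusted p = 5.04e-13) and 5.73% (adjusted p = 3.44e-12). These tests take genes as independent, although copies of a family can lie close together. They were not matched on expression, with which the called share rose, so they do not show an effect of the chromosome itself.

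Reads shared between overlapping genes could make neighbours change together, since strand was not marked. Of 105 overlapping opposite-strand pairs with a called member, 55.2% changed in the same direction, against 62.0% of 137 opposite-strand neighbours within 1 kb that do not overlap. The difference of -6.81 percentage points has a 95% interval from -19.3 to 5.7, so the test leaves open a small effect of shared reads. The bound written in advance took an interval that holds 0 as evidence against it, which was too weak, because such an interval does not exclude an excess of up to 5.7 points.

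Variants linked to the daf-2 mutation might add calls near that gene on chromosome III. Within 1 Mb of daf-2, 16 of 187 genes (8.56%) were called, against 79 of 1470 (5.37%) on the rest of the chromosome. The ratio of 1.59 has a 95% interval from 0.951 to 2.67, too wide to settle it.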
